A study of Arabidopsis thaliana with 41 samples.

How the data were processed

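The series holds 37 ChIP-seq samples and 4 bisulfite sequencing samples from Arabidopsis thaliana. They come from endosperm nuclei of F1 seeds of the reciprocal crosses Col x Ler and Ler x Col (mother written first) and from leaves of Col plants. Endosperm nuclei were isolated by INTACT, an affinity purification of tagged nuclei, per the labels' protocols. The 17 histone mark samples cover H3K27me3, H3K9me2 and H3K27me1 with 2 replicates per cross or tissue, except for leaf H3K27me1 with 1; the other 20 ChIP samples are H3 or input libraries. Per the labels' protocols, the leaf libraries of H3K27me3 and H3K9me2 used another library kit than the endosperm libraries and the leaf H3K27me1 library. Tissue and kit therefore cannot be told apart for those marks. By a series number in the sample titles, all H3K27me3 libraries belong to the same series. Leaf and Col x Ler H3K9me2 libraries belong to different series, and the Ler x Col libraries of H3K9me2 and H3K27me1 mix both. Comparisons between marks, tissues and crosses can therefore also differ in series.

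The deposited ChIP-seq files are 21 lists of enriched 150 bp windows, 7 per mark: 1 list for leaf and, for each cross, a total list, a COL list and a LER list. Bowtie, Bismark 0.7.8 and the genome build TAIR10 are named for all samples alike in the submitters' processing notes, which do not say which tool served which assay. How windows were called, against which control, how replicates were combined and how reads were assigned to alleles is not stated in the labels, and the deposited lists hold no score, height or replicate column. Read depth behind the lists is therefore unknown, and list comparisons have no replicate error. In every list the shortest run of adjacent windows was 300 bp.

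The deposited bisulfite files give, for each cytosine, whole-number counts of methylated and unmethylated reads, not split by allele. Filters, duplicate removal and the treatment of Ler sequence differences in the mapping are not stated there. Mean nuclear CG coverage was 6.47 and 5.81 reads in Col x Ler replicates 1 and 2, and 4.68 and 4.99 in Ler x Col replicates 1 and 2.

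Gene positions and names came from a gene table of assembly TAIR10.1, of which no coordinate is printed; all 122 list members were found in it by locus identifier. The share of C at gene starts and G at gene ends peaked at an offset of 0 bp in 21 of 25 chromosome segments (21.0% against 17.0% at other offsets), so the table was used on the TAIR10 positions of the files. The table has no strand, so where a region of 1 kb upstream had been planned, 1 kb on both sides was used. It has no transposable element class either, and pseudogenes were counted in its place.

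A gene was called marked when windows of a list covered at least 200 bp of its body (27444 nuclear protein-coding genes). The maternal allele is COL in Col x Ler and LER in Ler x Col. Maternal-only genes were marked on the maternal and not on the paternal allele in both crosses, and paternal-only, Col-only and Ler-only genes were defined alike. Assessable genes (3035) had an allele window of any mark over at least 200 bp in each cross. Leaf-only genes were marked in leaf and in neither cross; endosperm-only genes were marked in both crosses and not in leaf. A region is a run of adjacent windows, and it counted as shared when at least 50% of it was covered by the other list. Pericentromeres are the contiguous 100 kb bins around each centromere bounded by bins with over 50% leaf H3K9me2. Counts of list members were set beside 10000 random gene lists of the same size matched on gene length, and mark overlap beside 100 circular shifts within chromosomes; these are descriptions of the lists, without p-values.

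Methylation levels are methylated reads over all reads at sites with at least 4 reads in each of the 4 libraries. Cross differences of levels were tested with an exact two-sided permutation test, in which 2 against 2 libraries give no p below 0.333, and differences between region classes with an exact two-sided sign-flip permutation test over the 4 libraries, with a smallest p of 0.125. Both were adjusted by Benjamini-Hochberg over 15 and 21 tests. Counts of 500 bp windows and of gene regions (gene plus 1 kb on both sides) were tested between crosses with the quasi-likelihood test of edgeR 4.0.16 on methylated and unmethylated counts, with library effects and a cross effect, at Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 20 points (CG, CHG) or 10 points (CHH). Windows needed at least 3 sites (CG, CHG) or 5 (CHH), gene regions 5. Counts were simulated with an average spread per methylation level, taken from the libraries. On these, the window test recovered 32% of CG differences of 30 points and 93% of 50 points among 194838 windows. The recovery was 52% and 86% in CHG among 197403 windows, and in CHH 19% of 15 points and 55% of 25 points among 224163. The gene test recovered 100% of changed genes at each size in each context (27149, 27151 and 27281 genes). No unchanged window or gene was called in these simulations. They held no genome-wide difference between the crosses and no variation in spread between features of the same level. In CG, 4.98% of unchanged simulated genes had an unadjusted edgeR p under 0.05, against 4855 of 27140 genes in the real data. Recovery and false calls in the real data can therefore differ from these values.

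The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The 9 lists hold paternally expressed imprinted genes (32), maternally expressed imprinted genes (12), floral and flowering-time regulators (16), meristem regulators (13), embryo and seed maturation genes (16), endosperm regulators (9), seed coat genes (9, as a possible other cell type), photosynthesis genes (10) and housekeeping genes (5). Besides list members, the text names the 10 genes with a symbol and the longest marked body per H3K27me3 class, with 0 bp in the opposite class, and per context and direction up to 5 called genes with a symbol whose libraries do not overlap between crosses. The gene table gives a symbol to 10374 genes. The alternatives were a coverage of 1 or 500 bp, flanked genes, the longest 50% of the regions, other shared fractions, chromosome arms only, read minimums of 1 and 8, a mean over sites, limma 3.58.1 on log2 ratios with a pseudocount of 1, a replicate block, no minimum difference, 200 bp windows, no minimum number of sites, and leaving out each bisulfite library. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3.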

Results

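Chromatin of endosperm, the nutritive seed tissue with a double maternal and a single paternal genome dose, was profiled in reciprocal crosses of the accessions Col and Ler and in Col leaves. Windows enriched for H3K27me3, the mark of Polycomb repressive complexes, for H3K9me2, a mark of silent heterochromatin, and for H3K27me1, likewise a heterochromatin mark, were deposited per tissue and, in endosperm, per parental allele. Each histone mark had 2 replicates per tissue or cross except leaf H3K27me1 (1), and the deposited lists do not show replicates. DNA methylation was measured in endosperm in 2 libraries per cross, with 36011484 and 32353541 nuclear CG read counts in Col x Ler and 26049540 and 27786134 in Ler x Col. Of the nuclear CG sites, 37.7% had at least 4 reads in every library.

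The first comparison asked how endosperm and leaf differ in the location of the 3 marks. H3K27me3 in endosperm extended into pericentromeric heterochromatin, which was nearly free of it in leaf. Pericentromeres hold 12.1% of genomic windows; they held 1.38% of leaf H3K27me3 windows, 22.0% of those in Col x Ler and 21.8% of those in Ler x Col. Protein-coding genes held 51.4% of leaf H3K27me3 windows against 33.3% and 35.5% in the crosses, and pseudogenes held 2.83% against 22.9% and 22.8%. The total covered length was similar, at 16.5 Mb in leaf, 13.8 Mb in Col x Ler and 13.5 Mb in Ler x Col. H3K9me2 and H3K27me1 were mostly pericentromeric in both tissues: H3K9me2 at 54.8% in leaf, 59.9% and 56.9% in endosperm, H3K27me1 at 55.1%, 61.9% and 60.7%.

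**Figure D1:**
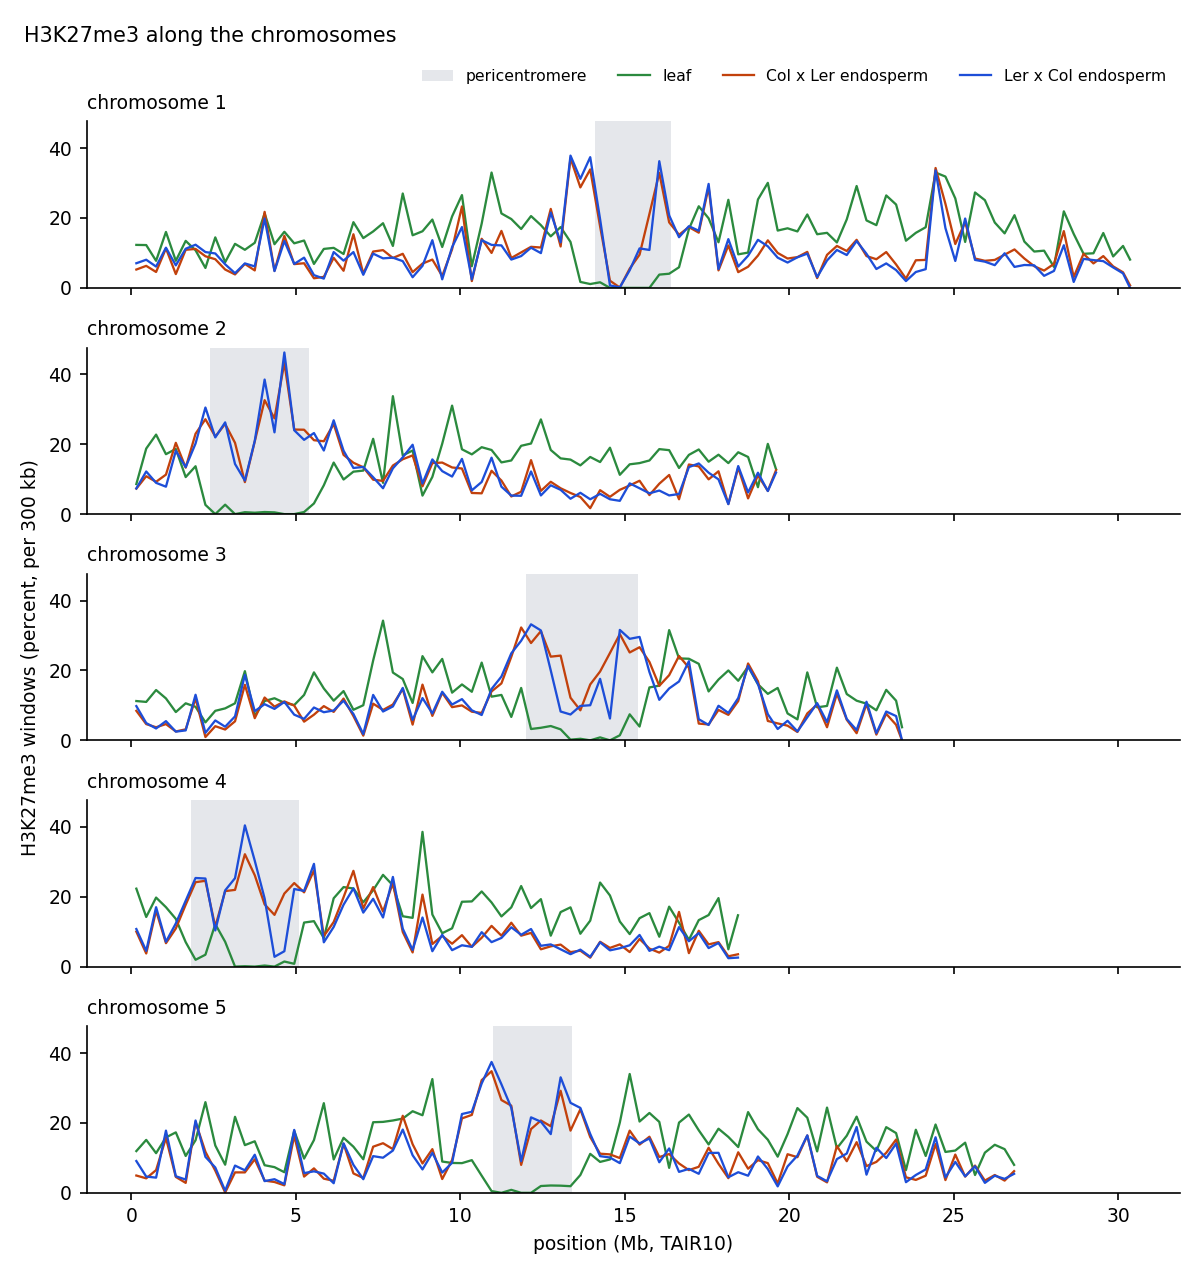
Share of 150 bp windows listed for H3K27me3 (percent, y axis) in 300 kb bins along the 5 chromosomes (position in Mb, TAIR10, x axis) in leaf and in endosperm of both crosses, with pericentromeres shaded. The leaf line falls to near 0 in most of the shaded parts, except in a stretch on chromosome 4, and the endosperm lines reach their highest values inside them or close to their edges.

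Of 13751 leaf H3K27me3 regions, 26.1% were shared with Col x Ler and 24.4% with Ler x Col endosperm, while 50.5% of the Col x Ler regions were shared with Ler x Col. Leaf regions of H3K9me2 (56.0% and 52.8%) and H3K27me1 (55.1% and 52.5%) were shared with endosperm more often. When sharing of 1 bp sufficed, the leaf H3K27me3 shares were 40.7% and 38.4%, and with 80% of the length required they were 17.0% and 15.8%. Tissue is confounded with library kit for H3K27me3 and H3K9me2, and the lists have no replicate error.

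Leaf H3K27me3 covered 6554 genes and endosperm of both crosses 3027; 2034 genes were shared, 3465 were leaf-only and 993 endosperm-only. The longest leaf-only coverage lay over ABCA3 (4458 bp), PPC4 (4297 bp), MLO14 (4287 bp), ABCB22 (4268 bp) and ABCB18 (4243 bp), 3 of these 5 being ABC transporter genes, followed by VEL2, which belongs to the vernalization gene family, ABCA5, TPS2, RHS6 and DIN2 (3835 bp). The longest endosperm-only coverage lay over ATRX, a chromatin remodeller gene, with 9174 bp in Col x Ler and 9924 bp in Ler x Col, and over SNL5, a co-repressor gene of the SIN3 family, with 7472 and 7408 bp. CIPK26 (4778 bp in each cross), ARABIDILLO-2 (4757 bp in each), ROPGEF14, PRL1, KAPP, the auxin response factor gene ARF6, LOX2 and ADT1 followed. All 10 of these endosperm-only genes also carried H3K9me2 in both crosses and 0 carried it in leaf; of the 10 leaf-only genes 0 carried endosperm H3K9me2 in both crosses. Short allele-list windows of 247 to 750 bp lay over 6 of the leaf-only genes, such as VEL2 (750 bp, paternal list of Ler x Col).

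Developmental regulators marked in leaf were leaf-only less often than the median of random leaf-marked lists, but within the central 95% of these. Leaf-only were 6 of 16 floral genes (random median 8 among leaf-marked genes, 12.5% of random lists below), 3 of 13 meristem genes (median 6, 1.19% below) and 5 of 16 seed maturation genes (median 9, 2.27% below). The shift was not particular to them. It was seen for leaf-marked seed coat genes (1 of 6, median 3, 1.23% below). Paternally expressed genes (5 of 25, median 13, 0.04% below) lay outside the central 95%. Maternally expressed genes and endosperm regulators had 4 of 6 each (median 3). All 16 floral and flowering-time regulators were marked in leaf and 9 of 16 in endosperm of both crosses (random median 1, 100% of random lists below). Marked in both tissues were AG, AP1, AP3, PI, STK, FUL, CAL, FLC and FT; STK had 4907 bp in leaf and in each cross, while the floral genes SEP1, SEP2, SEP3 and SHP2 had 0 bp in the endosperm total lists against 2920, 2151, 2288 and 3337 bp in leaf. All 13 meristem regulators were marked in leaf and 9 of 13 in endosperm, including the homeobox genes KNAT2 and WUS, the peptide gene CLV3 and PLT2, and excluding KNAT1, KNAT6, CUC1 and CUC3. All 16 embryo and seed maturation genes were marked in leaf and 8 of 16 in endosperm; ABI3 had 3816 and 3366 bp, while OLE2, SESA2 and EM1 had 0 bp in both crosses.

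Of 9 endosperm regulators, 6 were marked in leaf (99.54% of random lists below) and 1 in endosperm (ALE1, 522 and 222 bp), the random median being 1; MINI3 and IKU2, which promote endosperm growth, had 1799 and 1125 bp in leaf and 0 bp in both crosses. Of the 9 seed coat genes, 6 were marked in leaf and 3 in endosperm (TT8, TT1 and GL2). Of the 10 photosynthesis genes, 0 were marked in leaf and 2 in endosperm, RBCS2B (1165 bp in each cross) and RBCS3B (1505 and 1655 bp). None of the 5 housekeeping genes was marked by H3K27me3 in either tissue.

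The second comparison asked whether the marks occupy the same places. In endosperm, a large share of H3K27me3 windows was also listed for H3K9me2 and H3K27me1, and in leaf nearly none. For H3K9me2 the share was 4.15% in leaf, below the shifted median of 10.1%, but 40.7% in Col x Ler (shifted median 11.0%) and 43.5% in Ler x Col (10.6%). In pericentromeres 90.1% and 92.1% of the endosperm H3K27me3 windows carried H3K9me2, against 13.5% in leaf. In the arms the shares were 26.7% and 30.0% (shifted medians 4.64% and 5.15%), against 4.02% in leaf. For H3K27me1 the genome-wide shares were 0.427% in leaf, 36.4% in Col x Ler and 36.9% in Ler x Col, and the arm shares 0.418%, 21.2% and 21.7%. With the longest 50% of the regions, the leaf shares fell to 2.18% for H3K9me2 and 0.0689% for H3K27me1. Overlap of lists shows the same window in a population of nuclei, not the same nucleosome.

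**Figure D2:**
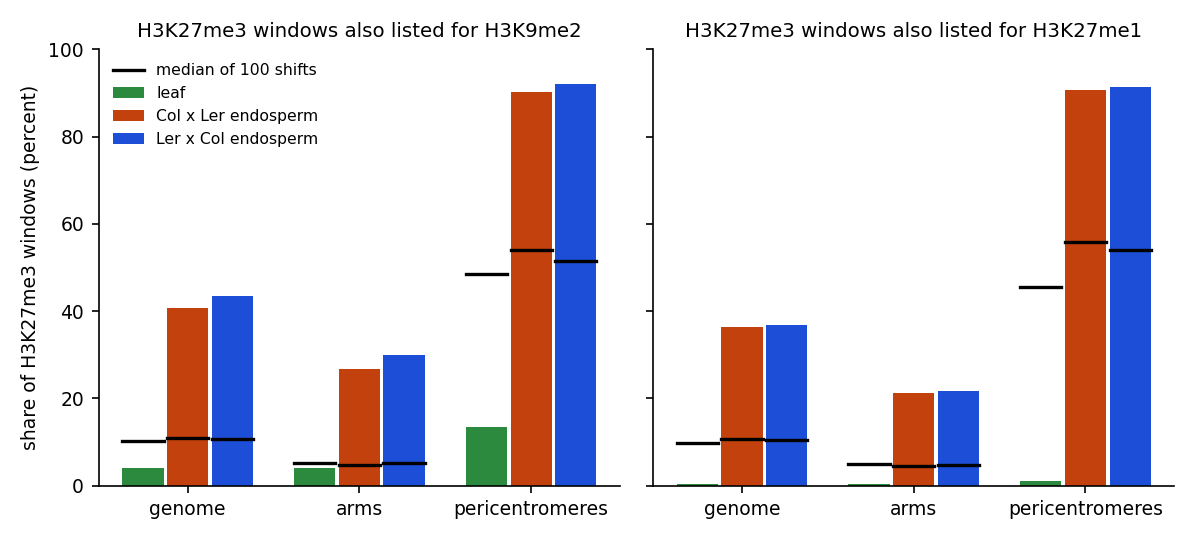
Share of H3K27me3 windows (percent, y axis) that were also listed for H3K9me2 (left) or H3K27me1 (right), for the whole genome, the arms and the pericentromeres, in leaf and both endosperm crosses. Black lines give the median of 100 circular shifts; the endosperm bars lie above them and the leaf bars below.

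The third comparison used the reciprocal crosses to separate parent of origin from accession. Among genes with the same H3K27me3 class in both crosses, the maternal-only class was the largest: 635 genes were maternal-only and 137 paternal-only, with 261 Col-only, 151 Ler-only and 330 marked on both alleles throughout. H3K9me2 had the same asymmetry in fewer genes, 225 maternal-only against 15 paternal-only, beside 208 Col-only and 61 Ler-only genes. Within a cross the H3K27me3 excess was smaller. Maternal-only were 1905 and paternal-only 1287 genes in Col x Ler, and 1664 and 1345 genes in Ler x Col. Most maternal-only genes of a single cross were thus not maternal-only in the other. In Col x Ler 2675 genes were marked on the maternal and 2057 on the paternal allele, whatever the other allele. In Ler x Col these were 2615 and 2296. H3K27me1 had 42 maternal-only and 64 paternal-only genes, an order that turned to 22 and 13 with 500 bp required, and an excess of Col-only (236) over Ler-only (100) genes. Of the maternal-only genes, 112 were shared between H3K27me3 and H3K9me2, against 47.1 for independent classes among assessable genes. The paternal-only count of H3K27me3 was 21 with 500 bp required, 70 with the longest 50% of the regions and 378 for flanked genes, and the H3K9me2 counts with 500 bp required were 119 maternal-only and 3 paternal-only, and with the longest 50% of the regions 73 and 4.

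**Figure D3:**
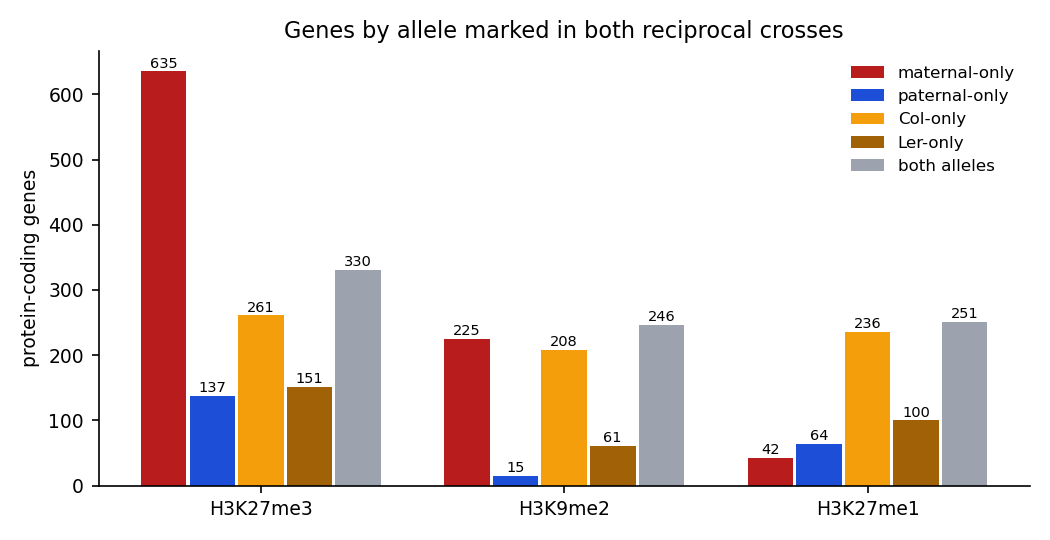
Number of protein-coding genes (y axis) per mark whose parental or accession class was the same in both reciprocal crosses. For H3K27me3, 635 genes were maternal-only and 137 paternal-only; for H3K27me1 the Col-only class (236) exceeded both.

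The maternal-only genes with the longest H3K27me3 coverage were led by VIM5, of a family that maintains CG methylation, with 3661 bp on the maternal allele in Col x Ler and 2250 bp in Ler x Col. They went on with the small RNA gene DCL4 (2007 and 3507 bp), ATRX (2400 and 3000 bp), the homeobox gene KNAT2 (3450 and 1950 bp), VIM1 (4135 and 1050 bp), RBP47A, PERK7, OPT7, the NAC transcription factor gene NAC007 (2375 bp in each cross) and COBL6. Of these 10 genes, 8 carried H3K9me2 in both endosperm crosses and 3 in leaf. Paternal-only coverage was shorter. It was longest over SFP1 (576 and 1350 bp on the paternal allele), JRG21 (1050 and 600 bp), the auxin response factor gene ARF12 (300 and 1200 bp), SCPL11, PAP21, ATS, FAR7, BLH2, ARF14 and UMAMIT19 (300 and 750 bp). Of the 10 paternal-only genes, 6 were marked in the total lists of both crosses, and SCPL11, FAR7 and ARF12 had 0 bp in both.

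Among all H3K27me3 windows of the allele lists, the maternal over paternal ratio was 2.05 in Col x Ler and 1.13 in Ler x Col (geometric mean 1.52). In the arms it was 2.21 and 1.41, and in pericentromeres 1.62 and 0.526. Maternal-only windows (11059) were 7.81% pericentromeric and 43.5% lay in leaf H3K27me3. Paternal-only windows (1698) were 43.2% pericentromeric, 15.8% lay in leaf H3K27me3 and 59.5% in endosperm H3K9me2 of both crosses, against 19.4% of the maternal-only windows. The ratio of windows for H3K9me2 was 1.88 in Col x Ler and 0.769 in Ler x Col, and for H3K27me1 1.89 and 0.744, so COL lists were longer than LER lists in both directions of the cross for these marks.

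Paternally expressed imprinted genes, whose active copy comes from the father, were often marked on the maternal allele. Of 24 assessable genes, 12 were maternal-only for H3K27me3 (random median 5, 99.89% of random lists below) and 0 were paternal-only. They were VIM5, the histone methyltransferase family gene SUVH7 (2082 and 1622 bp on the maternal allele), the auxin synthesis gene TAR1 (1028 and 1200 bp), the chromatin remodeller gene PKR2 (801 and 951 bp), ADM (795 and 767 bp), FXG1 (1543 and 1252 bp), AT4G11400, AT5G10950, AT1G66630, AT1G67820, AT1G60400 and AT3G49770. H3K9me2 was maternal-only over 11 of the 24 genes (random median 2, 100% of random lists below), and 9 genes were maternal-only for both marks, among them VIM5, SUVH7 and PKR2. YUC10 and PEG9 had long maternal coverage (1898 and 1448 bp, 1720 and 1270 bp) and 300 bp on the paternal allele of Col x Ler. AGL92 (300 and 1109 bp), AT5G62110 (300 and 1050 bp) and AT4G05470 (0 and 1001 bp) also had paternal coverage. So had, in Ler x Col, AT1G60410 (450 bp), PEG2 (430 bp), AT2G21930 (428 bp), AT5G63740 (325 bp), HDG3 (300 bp) and AT1G55650 (261 bp). With flanks of 1 kb the maternal-only count was 9, and with 500 bp required 15.

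In the total lists, 24 of the 32 paternally expressed genes carried H3K27me3 in endosperm of both crosses and 25 in leaf. H3K9me2 lay over 19 of 32 in endosperm and 4 of 32 in leaf. PHE1, a MADS-box gene, was covered over its whole 1080 bp in both crosses, but its allele lists had at most 186 bp, so it had no parental class. SUVH8, HDG3, NRPD1, MYB3R2, JMJ15, AL4, AT3G14205 and AT1G55650 were not marked in the endosperm total lists of H3K27me3. HDG3 and AT1G55650 had up to 300 bp in an allele list. Among 12 maternally expressed imprinted genes, 1 was marked in endosperm (ASK8, 459 bp in each cross) and 6 in leaf; MEA, FIS2 and FWA had 3652, 3686 and 3091 bp in leaf and 0 bp in the endosperm total lists. Only 3 of the 12 were assessable for allele, of which 0 were maternal-only.

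In the other lists, maternal-only H3K27me3 occurred over AP3 and FT (2 of 10 assessable floral genes, random median 2), KNAT2 and PLT2 (2 of 6 meristem genes, random median 1), ZOU (1 of 1 endosperm regulator), TT8 (1 of 4 seed coat genes) and RBCS3B (1 of 2 photosynthesis genes). Some of these calls rest on short coverage: AP3 and PLT2 had 300 bp on the maternal allele in each cross, the shortest run of any list. ZOU had 300 and 600 bp there, but 0 bp in the total list of Col x Ler and 300 bp in that of Ler x Col. The seed coat gene TT10 was paternal-only (450 bp in each cross), with 544 and 0 bp in the total lists. Of 5 assessable seed maturation genes 0 were maternal-only, and 0 housekeeping genes were assessable.

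**Figure D4:**
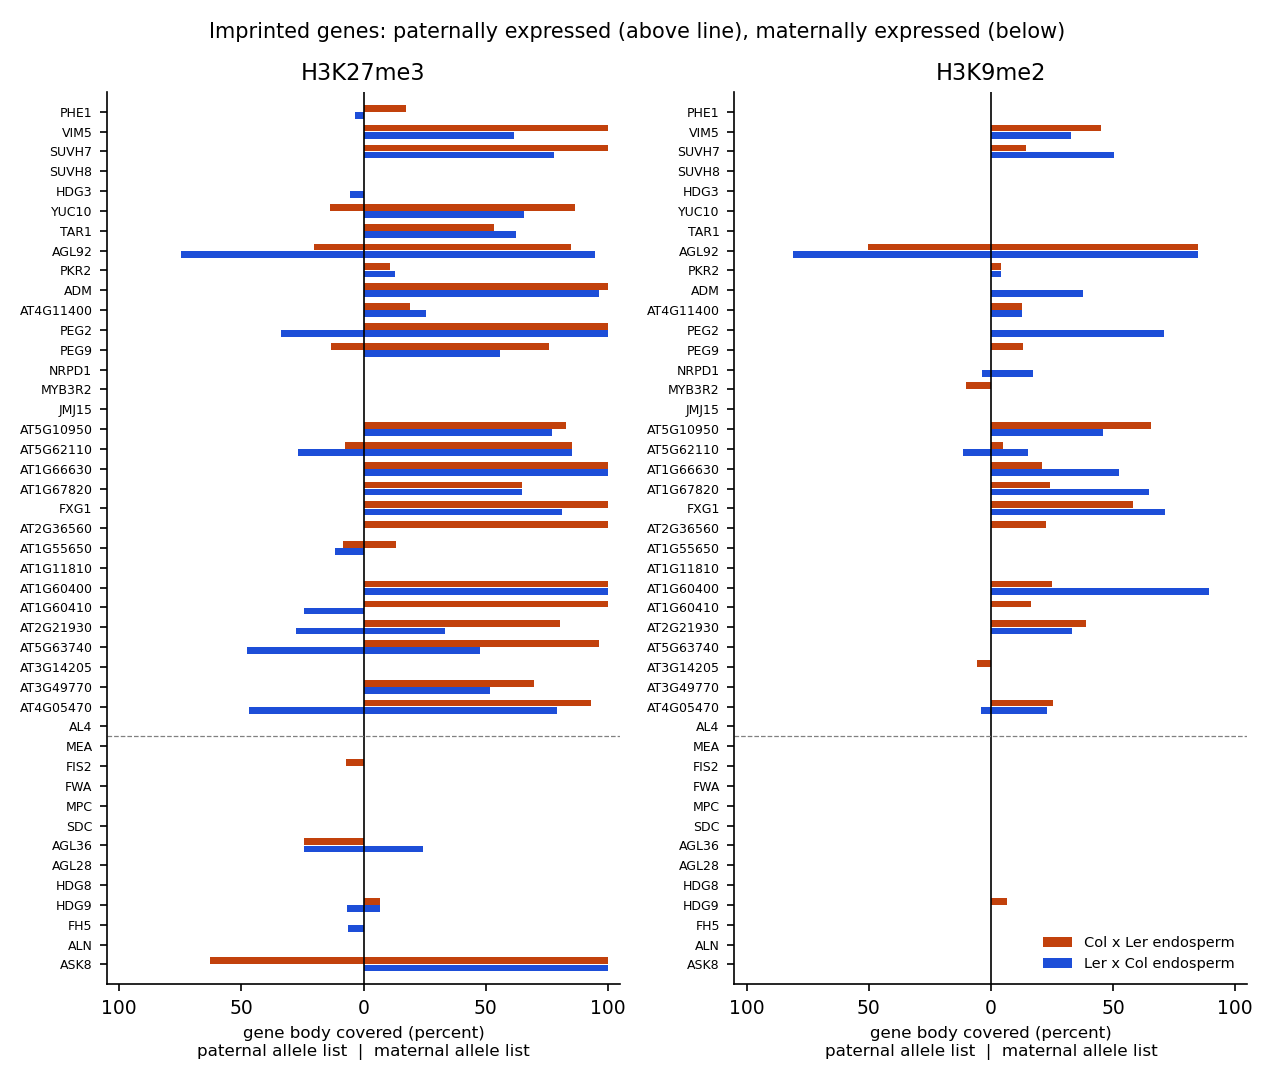
Share of the gene body (percent, x axis) covered on the maternal allele (to the right) and the paternal allele (to the left) by H3K27me3 and H3K9me2 for 32 paternally expressed (above the dashed line) and 12 maternally expressed imprinted genes, in both crosses. Most bars of the paternally expressed genes point to the maternal side, and AGL92 and AT5G62110, among others, have bars on both sides.

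The bisulfite libraries compared DNA methylation between the crosses. Genome-wide, endosperm of Ler x Col was more methylated than that of Col x Ler in every context, most of all in pericentromeres and pseudogenes. The CG level was 10.2% ± 0.00738 (SD, n = 2) in Col x Ler and 12.1% ± 0.0998 in Ler x Col, the CHG level 2.95% ± 0.00850 and 4.04% ± 0.127, and the CHH level 1.24% ± 0.0109 and 1.55% ± 0.0476. In pericentromeres CG levels were 36.4% ± 0.733 and 43.2% ± 0.309 (SD, n = 2), and CHG levels 17.0% ± 0.357 and 22.2% ± 0.522. Pseudogenes had 35.7% and 43.2% CG methylation and protein-coding genes 8.42% and 9.01%. The libraries of the crosses did not overlap in any of 15 comparisons of 5 regions and 3 contexts, but the exact two-sided permutation test of 2 against 2 libraries cannot give less than 0.333, its p in each case (adjusted p = 0.333). Chloroplast DNA, which is unmethylated, showed 0.538% to 0.588% methylated CG reads. The widest Wilson 95% interval of a genome-wide CG level was ± 0.0167 points, which covers counting error only. With a mean over sites in place of pooled reads, the CG difference was 0.903 points instead of 1.87, and the CHG difference 0.637 instead of 1.09.

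**Figure D5:**
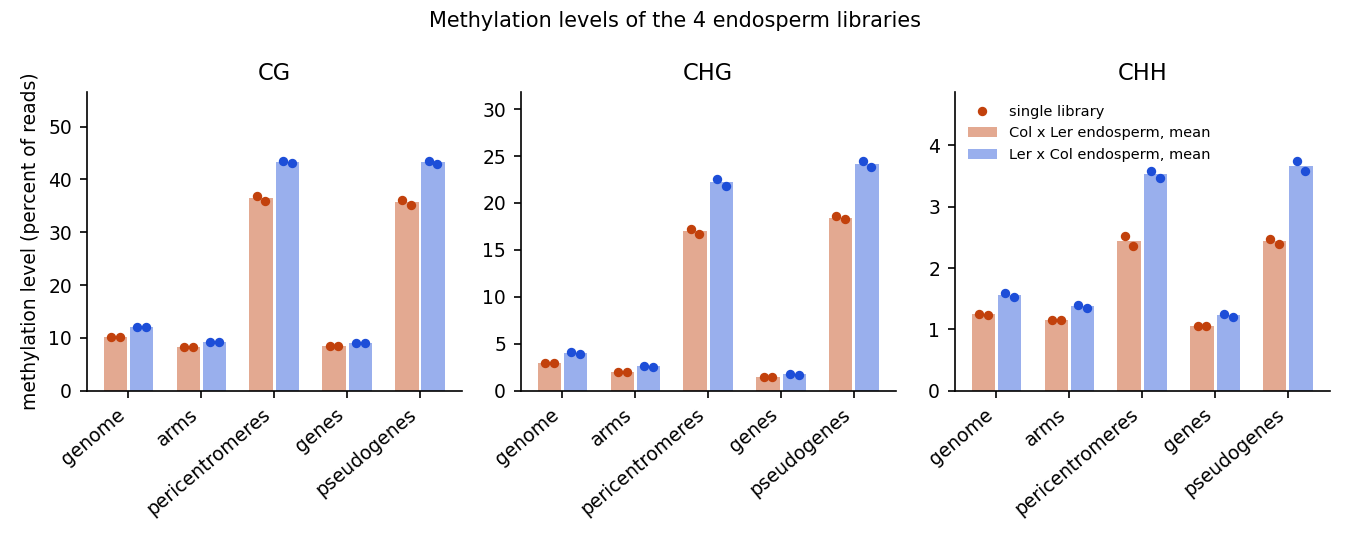
Methylation level (percent of reads, y axis) in CG, CHG and CHH contexts for the genome, arms, pericentromeres, protein-coding genes and pseudogenes. Bars are means of 2 libraries per cross and points the single libraries; in every group the Ler x Col points lie above the Col x Ler points.

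Methylation was then compared between classes of H3K27me3 regions. Maternal-only H3K27me3 windows were less methylated than those marked on both alleles or on the paternal allele alone. CG levels were 8.63% ± 0.796 (SD, n = 4) in maternal-only, 14.3% ± 1.41 in both-allele and 31.1% ± 3.73 in paternal-only windows, and CHG levels 6.50% ± 0.299, 12.3% ± 1.63 and 19.8% ± 3.37. In the arms alone the CG levels were 6.63%, 10.8% and 19.9%. Maternal-only windows were lower in 4 of 4 libraries in each of these comparisons and in CHH (1.58% against 1.97% and 2.76%). Each exact two-sided sign-flip permutation p was 0.13, the smallest that 4 libraries can give (adjusted p = 0.131 over 21 tests). The classes differed in H3K9me2 content too. Endosperm H3K9me2 of both crosses lay over 19.4% of maternal-only, 36.8% of both-allele and 59.5% of paternal-only windows. This content was not held fixed, so the difference cannot be credited to parental class alone.

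Endosperm H3K27me3 windows fell into a more and a less methylated part by H3K9me2. With H3K9me2 the CG level was 40.5% ± 3.25 (SD, n = 4) and the CHG level 22.6% ± 2.86, and without it 2.57% ± 0.112 and 2.38% ± 0.190. The latter CHG level was lower in Ler x Col (2.24%) than in Col x Ler (2.52%), opposite to the genome, as was that of maternal-only windows in genes (4.16% against 4.92%). Windows without any listed mark had 8.58% ± 0.355 CG methylation, more than H3K27me3 windows without H3K9me2 in 4 of 4 libraries, but less CHG (1.31%) and CHH methylation (1.16% against 1.28%), also in 4 of 4. Windows with H3K9me2 and no H3K27me3 had 46.0% ± 4.39 CG methylation, 4 of 4 libraries higher than with both marks. Their CHG level of 22.3% differed from that with both marks by less than its spread (difference 0.285 ± 0.393 points, SD, n = 4; exact two-sided sign-flip permutation p = 0.25, adjusted p = 0.25).

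Single 500 bp windows were tested between the crosses. The crosses differ in the dose of the Col and Ler genomes, and the counts are not split by allele. A called window or gene can therefore reflect accession, the mapping of Ler sequence or parent of origin, which the test cannot tell apart. By edgeR's quasi-likelihood test with adjusted p under 0.05 and the minimum difference, 491 of 174456 CG windows differed, 371 with higher and 120 with lower methylation in Ler x Col. Windows that were higher in Ler x Col had median levels of 9.43% and 38.9% (Col x Ler, Ler x Col), and 17.3% of them were pericentromeric (9.03% of tested windows) and 26.1% in pseudogenes (7.47% of tested). Windows that were lower in Ler x Col had medians of 33.0% and 6.84%, and 72.5% of them lay in protein-coding genes (63.8% of tested). In CHG, 52 of 176568 windows were called, all 52 higher in Ler x Col and 50.0% of them in pseudogenes.

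Examples chosen after their values were seen are a CHG window on chromosome 5 from 2035501 to 2036000 at AT5G06620, with 1.29% in Col x Ler and 35.3% in Ler x Col (edgeR adjusted p = 1.68e-06), and a CHG window on chromosome 3 from 11653001 to 11653500, outside genes, with 3.30% and 36.3% (edgeR adjusted p = 2.39e-11). A CG window on chromosome 1 from 24691001 to 24691500 at AT1G66245 had 59.2% in Col x Ler and 7.33% in Ler x Col (edgeR adjusted p = 0.00124). Of 222276 CHH windows edgeR called 0, with 13019 at unadjusted p under 0.05, and limma called 0. For CG windows limma called 0 and for CHG windows 9. Without Col x Ler replicate 1 or replicate 2, 0 CG and 0 CHG windows were called; without Ler x Col replicate 1 or 2, 93 and 83 CG and 0 and 1 CHG windows were.

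Among gene regions, 18 of 27140 differed in CG methylation by edgeR, 15 higher and 3 lower in Ler x Col, and 1 of 27124 in CHG. The only called gene with a symbol was ABCC15, an ABC transporter gene, with 9.08% ± 0.423 (SD, n = 2) in Col x Ler and 29.5% ± 1.80 in Ler x Col (log2 odds ratio 2.07 ± 0.280 SE, edgeR adjusted p = 2.17e-05). Genes without a symbol, chosen after their values were seen, include AT1G28180 (9.96% and 32.6%), AT5G06630 (10.0% and 31.3%) and, in the other direction, AT5G49250 (41.9% and 11.6%). AT2G07667 was called in both contexts, with 22.8% and 57.8% CG and 12.6% and 35.0% CHG methylation. Its CG read counts were 705 and 551 in Col x Ler and 238 and 253 in Ler x Col. The ratio of Ler x Col to Col x Ler reads was 0.391, against a median of 0.843 over gene regions. In CHH, edgeR called 0 of 27274 genes, with 3549 at unadjusted p under 0.05, and limma called 0; limma called 0 genes in CG and CHG too. Without Col x Ler replicate 1 or replicate 2, 4 genes were called in CG in each case and 0 in CHG, and without Ler x Col replicate 1 or 2, 19 and 21 in CG and 2 and 2 in CHG.

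Without the minimum difference, edgeR's adjusted p was under 0.05 for 1104 genes in CG (788 higher and 316 lower in Ler x Col), 289 in CHG and 233 in CHH. No member of the 9 fixed lists reached the minimum difference, whether adjusted over all genes or adjusted over the list alone. Of the 32 paternally expressed genes, 5 had an edgeR adjusted p under 0.05 in CG adjusted over the list alone and 5 over all genes tested: ADM (5.57% in Col x Ler, 0.163% in Ler x Col), AL4 (17.9% and 10.3%), PHE1 (1.96% and 4.00%), AT2G36560 (6.68% and 16.8%) and AT1G60410 (2.26% and 7.17%). Of the 12 maternally expressed genes, 3 had it in CG over the list alone and 2 over all genes, FIS2 (1.45% in Col x Ler, 4.60% in Ler x Col) and FH5 (11.2% and 6.55%). The median CG level was 2.87% in Col x Ler and 4.16% in Ler x Col over the paternally expressed genes, 1.51% and 1.21% over the floral regulators, and 1.32% and 1.43% over the seed maturation genes. In CHG the median over the paternally expressed genes was 4.40% in Col x Ler and 3.12% in Ler x Col, opposite to the genome; 4 members had an edgeR adjusted p under 0.05 adjusted over the list alone and 1 over all genes, PHE1 (5.35% and 1.99%). CG medians were 4.98% and 5.64% over the maternally expressed genes, 0.938% and 0.979% over the meristem regulators, 0.998% and 0.967% over the endosperm regulators, 3.98% and 4.41% over the seed coat genes, 3.10% and 3.82% over the photosynthesis genes, and 2.87% and 1.85% over the housekeeping genes.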

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

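The tests of conversion, depth, library kit and maternal dose were chosen only after the result they concern had been seen, and the others before.

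In pericentromeres the maternal over paternal ratio of windows pointed in opposite directions in the crosses for all 3 marks: it was 0.526 in Ler x Col and 1.62 in Col x Ler for H3K27me3, 0.687 and 1.90 for H3K9me2, and 0.717 and 2.07 for H3K27me1. The difference between the crosses was not tested, since the lists have no replicates. The mitochondrial cytosines, which no comparison used, showed methylation above the chloroplast level in all 4 libraries: 13.2% ± 1.82 (SD, n = 4) in CG, 7.00% ± 0.952 in CHG and 1.12% ± 0.0727 in CHH, against at most 0.588%, 0.592% and 0.680% in the chloroplast. This difference was not tested either. Median mitochondrial CG coverage was 0 reads in every library, and 25.5% to 28.8% of the CG sites had at least 4 reads. The levels therefore rest on a part of the sites, and the origin of these reads was not tested. Total mitochondrial CG reads were 131581 and 79125 in Col x Ler and 79447 and 75795 in Ler x Col. The methylated reads among them were 14286 and 12109, and 10526 and 10040, and so varied less than the totals. Methylation of mitochondrial DNA itself is therefore not shown.

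Genome-wide, endosperm of Ler x Col was more methylated than that of Col x Ler. The chloroplast CG rate differed by -0.0297 points between the crosses, which argues against incomplete conversion, and the CG difference was 2.15 points at sites with at least 8 reads in every library, which argues against low depth. If better mapping of Col reads made the difference, it should have been smallest in the 20% of pericentromeric windows with the highest read ratio of Ler x Col to Col x Ler; it was 8.29 points there and 1.95 points in the 20% with the lowest ratio, the opposite order. Lower methylation of the Col allele when Col is the mother stays open: windows covered at the dose of a lone Col allele (83) were 2.36 points lower in Col x Ler, against 1.83 points in ordinary windows, and the bound set before was wrong because it exceeded the difference to be explained. Why the difference grows with the read ratio was not tested. The windows with the lowest and the highest ratio also differed in level, with 30.6% and 43.9% CG methylation in Col x Ler. The read ratio test concerns better mapping of Col reads only. Other effects of Ler sequence on the mapping stay open as untested, as does a difference in maternal genotype or seed stage between the crosses.

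H3K27me3 entered pericentromeric heterochromatin in endosperm. Collapsed repeats may contribute: bisulfite reads per CG site were 1.43 to 1.63 times as high in pericentromeric windows with H3K27me3 as in those without, and the value expected under this explanation was passed in some libraries and missed in others. The library kit and the tissue cannot be told apart for H3K27me3, because all its leaf libraries used the other kit. H3K9me2, with the same change of kit, gained 3.53 points in pericentromeric share and H3K27me1, without it, 6.17 points, against 20.5 points for H3K27me3. The series number of the titles also differs between leaf and most endosperm libraries for H3K9me2, but not for H3K27me3. Lower DNA methylation at the marked windows was tested as a biological explanation. The CG level in pericentromeric H3K9me2 windows was 1.54 points higher, not lower, with H3K27me3 than without (48.4% against 46.8%, difference from 0.979 to 2.55 points in the 4 libraries). Over the whole genome it was lower with both marks than with H3K9me2 alone (40.5% against 46.0%, 4 of 4 libraries). Leaf methylation was not measured, and the counts are not split by allele. Whether methylation was lost relative to leaf, or on a single allele, therefore stays open.

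H3K27me3 windows were more numerous on maternal than on paternal alleles of the arms. If maternal genome dose raised the ratio alike everywhere, arms and pericentromeres would have the same ratio. It was 1.37 times as high in arms as in pericentromeres in Col x Ler and 2.67 times in Ler x Col. The bound for this test was lowered while the ratios were already known, and a stricter first draft was not met in Col x Ler. The lists hold calls without a score and of unknown read depth. A dose effect on the number of listed windows could therefore differ between arms and pericentromeres, and the test cannot exclude dose. Nuclei of maternal seed tissue could add maternal H3K27me3 at targets shared with leaf. INTACT should, however, remove untagged nuclei, and the tag came from the father in Ler x Col per the labels. The ratio in arms was 2.39 inside and 1.49 outside the leaf list, falling in both crosses. That of H3K9me2 (2.27 and 1.25) fell almost only in Ler x Col. That of H3K27me1 (0.819 and 1.16) rose in Col x Ler (0.691 to 1.72) and fell in Ler x Col (0.970 to 0.778). The 1.49 passed the bound set before (1.29, H3K9me2 in all arms), narrowly in Col x Ler (1.90 against 1.86) and by more in Ler x Col (1.17 against 0.90), but the lists give no spread to judge this by. Maternal dose, such nuclei and a parental difference in Polycomb marking all stay open.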

How the results depend on the processing

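All alternatives were planned, with 1 kb on both sides in place of 1 kb upstream. Of 229 comparisons with an alternative, 130 stayed within their bounds and 99 moved. Secondary counts and shares made up 73 of them, of which 26 stayed and 47 moved. Parental and tissue gene counts, which partly overlap with these, made up 71, of which 36 stayed and 35 moved. For the 63 comparisons of levels and regions, only the direction was judged. A fall of the CG difference from 1.87 to 0.903 points with a mean over sites thus counted as staying. The order of maternal-only and paternal-only H3K27me1 genes (42 and 64) turned with 500 bp required (22 and 13). Methylation levels and their differences between H3K27me3 classes kept their direction under each of their 63 alternatives, and the count of maternal-only H3K27me3 genes stayed between 584 and 789. For the results below the cause was not tested.

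Leaf H3K27me3 regions shared with Col x Ler and Ler x Col were 40.7% and 38.4% with 1 bp required, 17.0% and 15.8% with 80%, and 24.9% and 23.2% with the longest 50% of the regions. With the longest 50%, H3K9me2 shared 2.18% of leaf, 35.9% of Col x Ler and 39.7% of Ler x Col H3K27me3 windows, and H3K27me1 0.0689%, 32.2% and 33.5%. In arms only, H3K9me2 shared 4.02%, 26.7% and 30.0%, and H3K27me1 21.2% and 21.7% in the crosses.

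Numbers of calls between the crosses moved with most settings. Without a minimum difference, 996 CG and 142 CHG windows and 1104 CG, 289 CHG and 233 CHH genes were called. With at least 1 read per site, 1502 CG and 79 CHG windows and 0 CHG genes were called, and with at least 8 reads, which left 14945 CG windows to test in place of 174456, 53 CG, 9 CHG and 3 CHH windows, 4 CG and 0 CHG genes. With limma, 0 CG and 9 CHG windows and 0 CG and 0 CHG genes were called. With 200 bp windows, 20 CHG and 5 CHH windows were called. Leaving out 1 library gave 0 to 93 CG and 0 to 1 CHG windows, and 4 to 21 CG and 0 to 2 CHG genes; the lone library of a cross is then assumed to vary like the other pair. With the replicate number as a block, 346 CG, 29 CHG and 1 CHH windows and 18 CG, 1 CHG and 0 CHH genes were called. Deviations of same-numbered libraries were almost uncorrelated (from -0.0181 to 0.0242), so no pairing by number was seen. Counting error was not removed from these deviations and lowers such a correlation, so a pairing is not excluded. No paired analysis was possible for the ChIP-seq lists because they hold no replicate columns.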

Other observations

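Of the 24 paternally expressed genes with endosperm H3K27me3, 19 also carried H3K9me2 in both crosses, against 0 of 1 maternally expressed gene, 1 of 9 floral regulators, 0 of 9 meristem regulators and 1 of 8 seed maturation genes. The difference between the lists was not tested. AT1G11810 carried H3K27me3 over all of its 1304 bp and H3K9me2 over 600 bp in both crosses, with 0 bp in the H3K27me3 allele lists.

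H3K27me1 covered 3442 genes in leaf and 809 in endosperm of both crosses, with 2644 leaf-only and 264 endosperm-only genes. H3K9me2 covered 2763 and 1134, with 1990 leaf-only and 494 endosperm-only genes. With 500 bp required the leaf-only counts were 1199 for H3K27me1 and 912 for H3K9me2. With the longest 50% of the regions they were 965 and 807, and the endosperm-only counts 175 and 288. For H3K27me1 leaf and endosperm libraries used the same kit but differed in genotype, and the leaf library had no replicate.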
